A study of Mus musculus with 32 samples.

How the data were processed

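Lung RNA, taken from part of each animal's lung, was measured on Affymetrix mouse genome arrays, with 1 array per mouse and 32 arrays in 10 groups, per the labels. The groups combine genotype (Gsr-WT or Gsr-KO, both C3H/HeN), age (E19, P5, P56) and, after birth, air or 100% oxygen from day 0 to day 5, with 4 arrays in each E19 group and 3 in each other group. Arrays were grouped from the labels alone. The deposited values are intensity on a linear scale for 45101 probe sets; MAS5 is named as the processing tool per the labels. The mean of each array's values without the lowest and highest 2% was the same on every array, as read from the values. No detection calls, software version or scan dates are given, and sex is not among the labels. The number of arrays limits the precision of every value.

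The values were computed on in R 4.3.3 with limma 3.58.1. An offset of 26.3, the 25th percentile of all values, was added before log2. No further scaling was done, because the array medians differed 1.82-fold, under the 2-fold set as the limit for it. A probe set was kept where it exceeded the median of all values, 100.4, on at least 3 arrays, which left 27089, of which 23428 carried exactly 1 gene symbol. The 64 control probe sets, 9211 without a symbol and 932 with several were not tested. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 13345 genes, 5968 of them with more than 1 kept probe set. Of 337 other probe sets of the called genes under the naming rule 28 changed in the opposite direction.

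All 32 arrays entered 1 limma fit with a mean per group and 22 residual degrees of freedom, with a trended variance prior (eBayes, trend=TRUE). The 13 comparisons were contrasts of this fit, tested two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. They are KO against WT in each of the 5 conditions, hyperoxia against air in each genotype at P5 and P56, the genotype-by-oxygen term at either age, and WT in air between successive ages. The groups of 3 or 4 arrays share the estimate of the spread, so a fit of the compared groups alone is given beside the counts it changes most. Gsr was also tested by exact permutation of the arrays within each condition. Positions on GRCm38.p6 served only to find the neighbours of Gsr within 10 Mb, which were compared with all other genes by Fisher's exact test, two-sided, with windows of 5 and 20 Mb beside it.

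Lists of genes for cell types, pathways and tissues other than lung were set, 44 in number with a sex-linked list. Those with at least 3 measured genes, without the sex-linked list, were tested with camera. The preset inter-gene correlation was 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The sex-linked list was given by array and not tested. An estimated correlation was used beside it, and fry as another set test. Called members were counted over all genes and adjusted over the list alone. The list level of an array is the mean over the list of log2 values centred on each gene's mean over all arrays. Genes were named by a rule: Gsr; the 10 highest and 10 lowest changes among called genes whose groups do not overlap (called genes alone for the genotype-by-oxygen terms), leaving out predicted and clone-named genes; and up to 4 called members of each called list or list with at least 3 called members. The comparisons, lists, filter, offset, naming rule and the alternatives not marked as added were chosen before the data were examined.

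The fit was tested on simulated data with known changes. The simulated noise was normal, independent between genes and arrays, and of equal spread on all arrays. The real arrays differ from this, with estimated array weights from 0.047 to 10.4. The shares below describe that setting and are not the error or power of the real tests. For KO against WT at E19, 14.9%, 64.2% and 97.0% of 67, 67 and 66 genes changed by log2 0.5, 1 and 2 were recovered, and 3.31% of calls were false. For hyperoxia against air in WT at P5 the shares were 7.46%, 50.7% and 93.9%, and for the genotype-by-oxygen term at P5 4.48%, 28.4% and 74.2%. The share of false calls ran from 1.85% to 7.38% over the comparisons and was above the threshold for KO against WT in P5 air (7.27%), P5 hyperoxia (7.38%) and P56 hyperoxia (6.72%) and for hyperoxia in KO at P56 (7.27%). Replicate numbers were checked for pairing: of 34 pairs of arrays with the same number in compared groups 10 correlated above 0.1 (range -0.41 to 0.27), and of 11 pairs of groups 1 had every correlation above 0.1, so the arrays were treated as unpaired and a replicate block was an alternative.

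The alternatives were no filter and a stricter filter, other offsets, quantile normalization, centring on array medians, every kept probe set on its own, the compared groups alone, no variance trend, array weights, the replicate block, the level of Y-linked genes as a covariate and each array left out in turn. Alternatives chosen after the data were seen were the liver transcript level or the mean 3'/5' ratio of the actin and Gapdh control probe sets as a covariate, a fit of the ages compared, and fits without 2 P5 arrays that stood apart from their groups, without 2 arrays of high 3'/5' ratio, and without all 4, and the lists tested with each array left out.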

Results

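Lung RNA of C3H/HeN mice was profiled on Affymetrix mouse genome arrays in animals with glutathione reductase (Gsr-WT) and in animals without it (Gsr-KO). Glutathione reductase returns oxidised glutathione to its reduced form with NADPH. Lungs were taken at embryonic day 19 (E19), at postnatal day 5 (P5) and at postnatal day 56 (P56). The postnatal mice had breathed room air or 100% oxygen (hyperoxia) from day 0 to day 5. There were 4 arrays per genotype at E19 and 3 in each postnatal group, 32 arrays in 10 groups. The deposited signals of an array summed to between 31173000 and 35272000 units, and the median signal lay between 68.4 and 124.6. The number of arrays limits the precision of each value. A change is a log2 difference with its standard error (SE), "called" means a limma adjusted p under 0.05 over 13345 genes, and gene lists were tested with camera. Where every array of a group lay under 100.4 units, the median of all values, the size of a change depends on the offset added before log2, and "at least" gives it with that group set to the median.

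The Gsr probe sets show whether the arrays carry the genotype on their labels. The tested probe set read 169 ± 32.8 in KO against 702 ± 105 in WT at E19 (SD, n = 4 and 4), a change of -1.90 (SE 0.16). The change was -1.80 in P5 air and -2.31 in P5 hyperoxia (n = 3 per group). It was -2.35 in P56 air and -2.38 in P56 hyperoxia (n = 3 per group). Over all ages and exposures the 16 WT arrays lay between 498 and 1541 and the 16 KO arrays between 138 and 257. The other probe set lay between 260.0 and 1107 in WT and between 21.0 and 106 in KO. The two-sided exact permutation p was 0.0286 at E19 for both probe sets, and with 3 arrays per group it cannot go below 0.1.

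Saraf, a regulator of store-operated calcium entry that lies close to Gsr on chromosome 8 (GRCm38.p6), was higher in KO than in WT in every condition. It read 5322 ± 472 in KO against 2363 ± 417 in WT at E19 (SD, n = 4 and 4). The changes were 1.17 at E19, 1.12 in P5 air, 1.34 in P5 hyperoxia, 0.82 in P56 air and 1.23 in P56 hyperoxia, all called. In P56 air Saraf lost its call without any 1 of the 6 arrays compared, with quantile normalization (0.74, adjusted p = 0.0923), without the variance trend (0.0688), with a replicate block (0.050027), in a fit of the P56 groups alone (0.0974) and without 2 P5 arrays described below (0.0754); its adjusted p was lowest with array weights (4.31e-06) and highest, 0.226, without KO replicate 1. In P5 air the call ended with the liver transcript level as a covariate (adjusted p = 0.559, and 2.21e-11 to 0.559 over the alternatives) and, as did that of Gsr, in a fit of the 2 groups alone (0.162), and in P56 hyperoxia in a fit of the 2 groups alone (0.696, range 2.04e-09 to 0.696). Of 69 tested genes within 10 Mb of Gsr, 2 were called in P56 air, Saraf and Pomk, against 5 of 13232 elsewhere (Fisher's exact p = 0.000548). In P5 air it was 1 of 69 against 0 of 13232 (Fisher's exact p = 0.00519), where limma gave 741 genes at an unadjusted p under 0.05, and in P56 hyperoxia 1 against 2 (Fisher's exact p = 0.0155). At E19 the neighbours were called no more often than other genes, 15.9% against 15.1% (Fisher's exact p = 0.866). In P5 hyperoxia 1 of 69 was called against 23 of 13232 (Fisher's exact p = 0.117, and 0.0442 within 5 Mb).

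**Figure D1:**
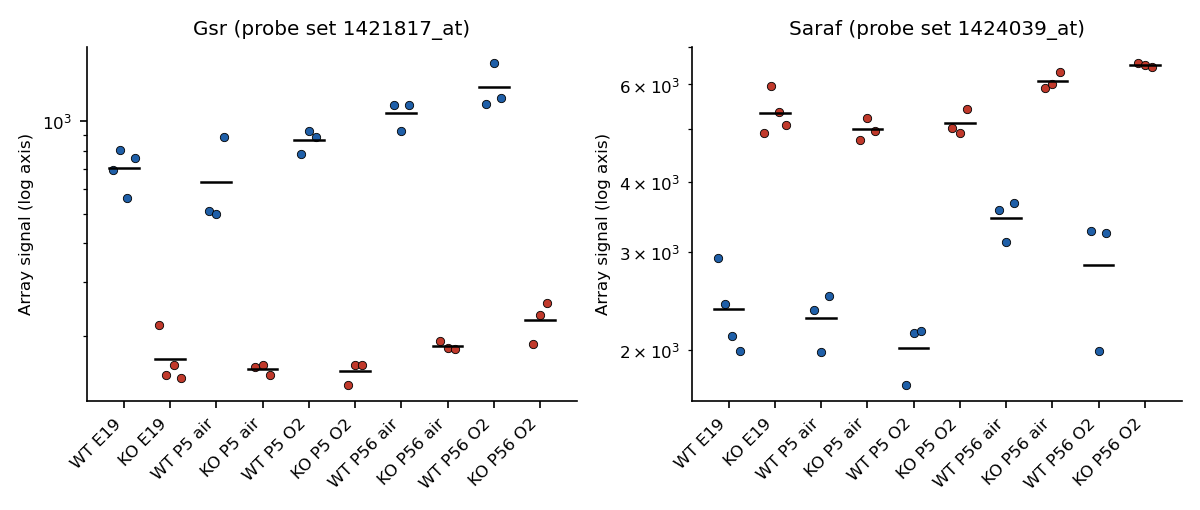
Array signal (log axis, signal units) of Gsr and of Saraf in each of the 10 groups; points are single arrays and bars are group means. KO arrays reach at most 257 for Gsr, where WT arrays start at 498, and Saraf lies between 4764 and 6556 in KO arrays and between 1725 and 3679 in WT arrays.

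Before birth, KO lungs carried more RNA of the gas-exchange cells than WT lungs. Rtkn2, a marker of alveolar type 1 cells, read 2606 ± 709 in KO and 399 ± 58.2 in WT (SD, n = 4 and 4), a change of 2.60 (SE 0.15). Of 24 measured type 1 genes 11 rose and none fell (12 and 2 adjusted over the list alone), among them Col4a3 by 1.83. Of 15 aerocyte genes, the capillary cells that face the airspace, 7 rose (8 adjusted over the list alone), with Car4 at 1.601, Chst1 at 1.55 and Igfbp7 at 0.72. Type 2 cell genes rose in 8 of 23 cases and fell in 1 (12 and 2 adjusted over the list alone), with the surfactant protein gene Sftpa1 at 1.08, the lipid desaturase Scd1 at 1.28 and Chil1 at 2.08. Endothelial genes rose in 8 of 31 cases (9 adjusted over the list alone), including the receptors Ptprb at 1.09 and Tek at 1.13, and club and secretory genes rose in 7 of 18 cases and fell in 2 (7 and 2 adjusted over the list alone), with Chad at 2.78 (at least 1.75) and Cyp4b1 at 1.30. The mean changes were 0.42 for type 1, 0.51 for aerocyte and 0.33 for type 2 genes, with camera adjusted p of 8.73e-06, 1.42e-05 and 0.000119. None of these calls held with an estimated correlation, where they had adjusted p of 0.167, 0.123 and 0.259; the endothelial and club lists had adjusted p of 0.400 and 0.396 there. With the liver transcript level as a covariate the means of type 1, aerocyte and type 2 genes were 0.23, 0.28 and 0.21, still called, with a 95% interval of -0.11 to 0.52 for type 2. The endothelial mean went from 0.28 to 0.0137 and the club mean from 0.73 to 0.12, and neither list was called (camera adjusted p = 0.104 and 0.0685). The endothelial mean was 0.15 without WT replicate 4 and 0.46 without KO replicate 1.

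Genes of dividing cells were lower in KO lungs at E19. Of 35 mitotic genes 31 fell (34 adjusted over the list alone), with Birc5 at -1.77, Aurkb at -1.66, Aurka at -1.53 and Nusap1 at -1.31. Birc5 read 488 ± 262 in KO and 1630 ± 477 in WT (SD, n = 4 and 4). Of 36 DNA replication genes 30 fell (32 adjusted over the list alone), with the licensing factor Cdc6 at -1.66, the primase Prim1 at -1.33 and the ligase Lig1 at -1.28. The mean changes were -1.20 and -0.90 (camera adjusted p = 4.88e-25 and 4.18e-17; adjusted p = 0.116 and 0.123 with an estimated correlation).

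Transcripts of red cell precursors and of liver were also lower in KO at E19. Of 23 erythroid genes 15 fell (16 adjusted over the list alone), with the blood group genes Kel at -2.79 (a fall of at least 2.55), Ermap at -2.62 and Rhd at -1.98 (mean -1.38, and -0.58 with the liver covariate; camera adjusted p = 1.40e-09; adjusted p = 0.171 with an estimated correlation). The liver plasma protein genes Ahsg, Apoa1 and Ttr fell by 4.88, 4.42 and 3.92 on the log2 scale. Ahsg read 17071, 8590 and 20770 in WT replicates 2, 3 and 4, but 141 in WT replicate 1 and at most 497 in KO. The mean erythroid level moved with it, at 1.25 to 2.32 in those 3 WT lungs and at -0.02 in WT replicate 1. The mitotic level of WT replicate 1 was 1.08, within the 0.86 to 1.29 of the other WT lungs, and in KO it ran from -0.53 to 0.39. Of 24 neutrophil genes 5 fell, with the granule genes Mpo at -2.86 and Elane at -2.30 (a fall of at least 1.09), and 4 rose (6 and 6 adjusted over the list alone), and the list was not called (mean -0.44, camera adjusted p = 0.748; mean 0.20 with the liver covariate). Of 26 heart and skeletal muscle genes 5 rose (7 adjusted over the list alone; mean 0.87, camera adjusted p = 0.00614; adjusted p = 0.613 with an estimated correlation), and with the liver covariate the mean was 0.40 and the list not called. The list also lost its call without WT replicate 2 (0.60) or 3 (0.53) and without KO replicate 3 (0.55) or 4 (0.44), and its mean was 1.52 without WT replicate 1. Myl3 was at 3.60, Tnni3 at 2.04 and Myh6 at 1.88, whereas the heart gene Myl7 was at 0.25 and not called, and Tnni3 read 14241 and 12785 in KO replicates 3 and 4, 4427 in WT replicate 1 and at most 1434 in the others.

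Enzymes that use or make glutathione went both ways at E19. Of 19 glutathione S-transferases 6 fell (8 adjusted over the list alone), with Gstt1 at -1.46, Gstt2 at -1.26, Gstz1 at -1.37 and Gsta3 at -1.98 (camera adjusted p = 0.00164; adjusted p = 0.273 with an estimated correlation). Of 29 measured targets of NRF2, the oxidant-response factor, 5 fell and 1 rose, with Osgin1 at -1.65, the transporter Abcc2 at -2.38 (a fall of at least 0.32) and Blvrb at -1.39, and the list was not called (camera adjusted p = 0.129). Among 23 genes of glutathione synthesis and transport 3 rose and 3 fell; Ggct changed by 0.70 and Gclm, part of the rate-limiting ligase, by -0.59 (another probe set 0.10). Interferon response genes rose in 18 of 36 cases (19 adjusted over the list alone), with Ifit1 at 2.54, Gbp3 at 2.39, Ifit3 at 1.95 and Xaf1 at 1.12 (camera adjusted p = 9.23e-15; adjusted p = 0.135 with an estimated correlation). The mean interferon level of KO replicate 2 was 1.32, against -0.30 to 0.19 in the other KO lungs and -0.85 to -0.53 in WT, and without that array the mean change of the list was 0.61 instead of 0.96.

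At E19 limma called 2023 genes, 922 higher and 1101 lower, of which 707 changed over 2-fold. The share of each direction moved with the scaling of the arrays: quantile normalization gave 1246 higher and 829 lower, and centring on the array medians 1450 and 676. In a fit of the E19 arrays alone 40 genes were called, all among the 2023, including Gsr, Rtkn2, Chst1, Chil1, Ifit3, Lyz1 and Nusap1. Without WT replicate 4 the count was 1140; array weights gave 1287, and with the liver transcript level as a covariate, chosen after the data were seen, 248 were called. KO replicate 1 had a mean log2 3'/5' ratio of the actin and Gapdh control probe sets of 4.37, against -0.01 to 0.57 in the other KO lungs.

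**Figure D2:**
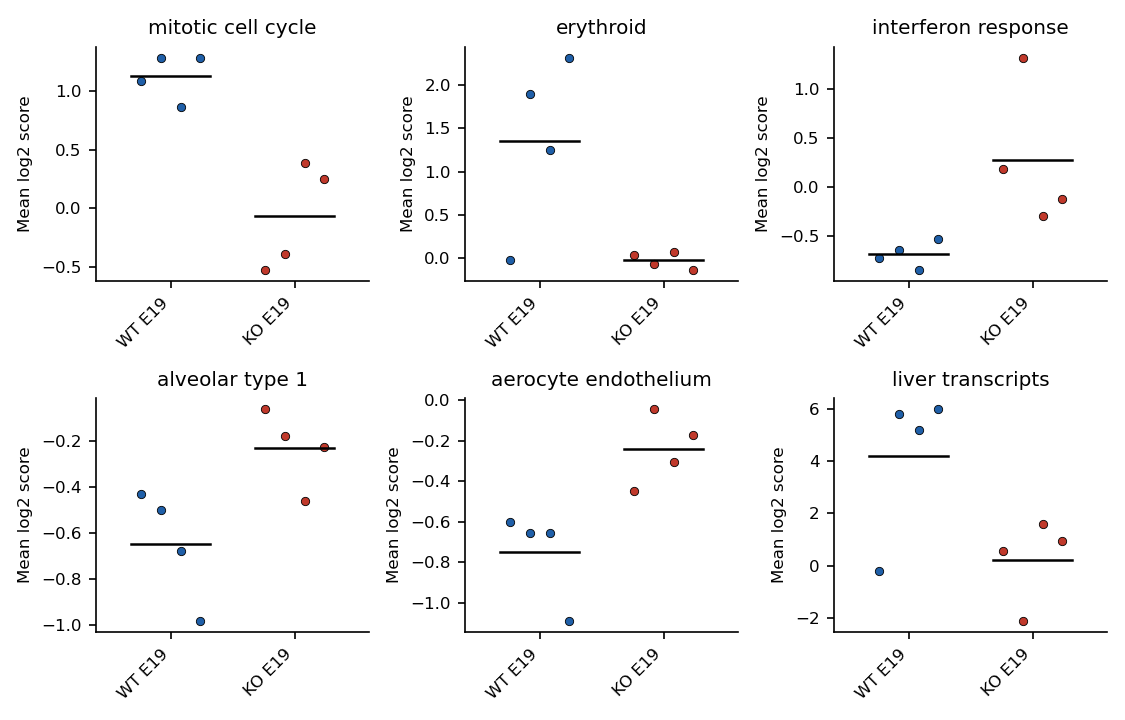
Mean level per array (log2 units, centred on the mean of all arrays) of gene lists at E19 in 4 WT and 4 KO lungs, with bars at group means. The mitotic level lies between 0.86 and 1.29 in WT and between -0.53 and 0.39 in KO.

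The genotype comparison in neonates kept in air asked what the missing enzyme changes without added oxygen. At P5 limma called 2 genes, Saraf at 1.12 (SE 0.16) and Gsr at -1.80 (SE 0.18; n = 3 and 3), with 741 genes at an unadjusted p under 0.05. As sets, DNA replication (mean -0.47), mitotic (-0.38) and NRF2 target genes (-0.30) were lower in KO, and HIF targets, which low oxygen induces, were higher (0.35). Their camera adjusted p were 5.71e-17, 1.43e-10, 4.33e-05 and 1.27e-06, and with an estimated correlation their adjusted p were 0.238, 0.248, 0.248 and 0.248. Liver transcripts separated these groups too, with levels of 2.48 to 4.40 in WT and -2.08 to 0.22 in KO. With that level as a covariate the 4 means were -0.35, -0.23, -0.35 and 0.41, still called, and 13 of the 20 list calls held. The control probe set for the 5' part of 18S ribosomal RNA separated the groups as well, at 16417 to 19030 in WT and 229 to 1867 in KO, a difference for which the list changes were not adjusted. KO replicate 1 stood apart: its HIF level was 0.55 against -0.24 and -0.45 in the other KO lungs, its mitotic level 0.22 against 0.92 and 0.96, and the array closest to it was KO E19 replicate 2 (r = 0.976). Within its own group its r was at most 0.961, and whether its age label is right was not tested. Without KO replicate 1 the mean changes were 0.0505 for HIF targets (not called), -0.14 for mitotic and -0.18 for DNA replication genes; without KO replicate 3 that of HIF targets was 0.55. Without WT replicate 3 the mean of the NRF2 targets was -0.0976 and their call was lost. Without that array 4 genes were called and without KO replicate 3, 5; a fit of the P5 groups alone called 64, and a fit of the 2 groups alone called 0.

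In WT neonates hyperoxia raised the p53 targets as a set, with a mean of 0.47 over 28 measured genes (camera adjusted p = 5.92e-11; adjusted p = 0.0369 with an estimated correlation). Immediate early genes, which cells switch on within minutes of a stimulus, were higher by 0.62 on average (camera adjusted p = 5.36e-21; adjusted p = 0.00317 with an estimated correlation), and 7 of 20 were called adjusted over the list alone. NRF2 targets were higher by 0.36 (camera adjusted p = 2.33e-09; adjusted p = 0.0918 with an estimated correlation) and mitotic genes lower, with a mean of -0.34 (1.03e-10; adjusted p = 0.218 with an estimated correlation). Liver transcripts fell as well, from levels of 2.48 to 4.40 in air to -0.07 to 1.46 in hyperoxia. With the liver covariate the means of p53, immediate early, NRF2 and mitotic genes were 0.36, 0.51, 0.32 and -0.24, still called, and 15 of the 22 list calls held. By fry 1 of the 22 lists was called. Without WT air replicate 3 the means were 0.71 for p53 and 0.55 for NRF2 targets, and without WT air replicate 2 that of mitotic genes was -0.22. Over all genes limma called Chodl alone, a lectin gene, at 1.23 (SE 0.21, 489 ± 86.6 against 194 ± 44.6, SD, n = 3 and 3), with 413 genes at an unadjusted p under 0.05. The call ended without a filter, with no offset, with quantile normalization or median centring and with the replicate block. It also ended in a fit of the compared groups alone and with the Y-linked or liver level as a covariate.

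One of the 3 WT air arrays carried p53 target levels of the exposed lungs. Cdkn1a, the p53-induced inhibitor of the cell cycle, read 848 and 840 in WT air replicates 1 and 2, 6352 in replicate 3, and 6329 to 8589 in WT hyperoxia. The p53 list level was 0.50 in that array, -0.24 and -0.23 in the other air lungs and 0.44 to 0.53 in hyperoxia. Among KO hyperoxia lungs, replicate 1 had a p53 list level of -0.16 and a Cdkn1a signal of 1296, where replicates 2 and 3 had 0.57 and 0.56, and 8384 and 8155. Without both arrays, an alternative chosen after the data were seen, 17 genes were called in WT. They included Cdkn1a at 3.03, the death receptor Eda2r at 2.86 and Zmat3 at 1.61, and the NRF2 targets Hmox1 at 1.39, Slc7a11 at 1.34 and Gclc at 1.18. These genes, like Cdkn1a and those given for KO in this fit below, were chosen after their values were seen. Of the p53 targets 6 of 28 and of the NRF2 targets 4 of 29 were then called; both arrays were left out for their levels of these targets, so more calls among them follow from that choice. Without WT air replicate 3 alone 7 genes were called, and without WT air replicate 1 or 2, or WT hyperoxia replicate 2 or 3, 0 were called by limma.

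In KO neonates hyperoxia came with high levels of striated muscle and squamous epithelium genes. Tnnc2, a fast skeletal troponin, read 3785 ± 294 in hyperoxia and 41.8 ± 46.2 in air (SD, n = 3 and 3), a change of 6.03 (SE 0.99), or of at least 5.23, as all air arrays lay under the median. The same holds for the myosins Myh8 and Myh1 at 5.34 and 4.88 (at least 5.12 and 3.44), the troponin Tnnt3 at 4.73 (at least 3.67), Krt13 and Krt4, keratins of stratified epithelium, at 5.52 and 5.23 (at least 4.47 and 5.02), and Krt5 at 2.77 (at least 2.49). Of 16 basal and keratinised epithelium genes 6 rose (10 adjusted over the list alone; camera adjusted p = 7.64e-19; adjusted p = 0.0277 with an estimated correlation). Of 26 heart and skeletal muscle genes 9 rose (9 adjusted over the list alone), with a mean of 1.01 and a median of 0.03 (camera adjusted p = 1.09e-05; adjusted p = 0.418 with an estimated correlation). All 3 KO hyperoxia lungs carried them: the squamous level was 2.07 to 2.62, against -0.81 to -0.13 in KO air. WT air replicate 1 had 2.40, with 2875 units of Krt13, and a striated muscle level of 2.60. WT hyperoxia replicate 3 had a muscle level of 2.19 with a squamous level of -0.46. Outside tissue as a source of these genes stays open, as set out below.

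**Figure D3:**
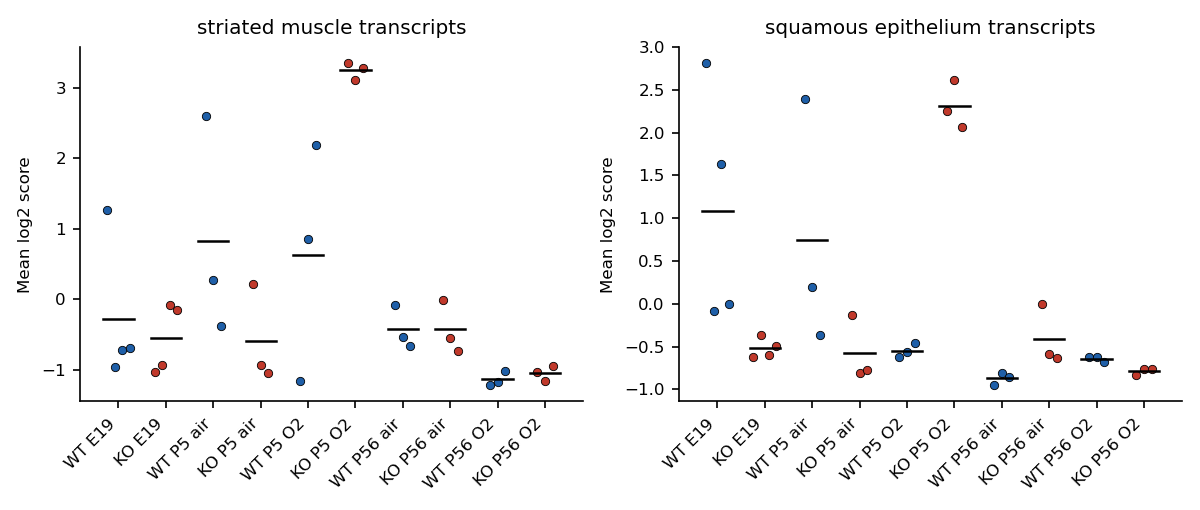
Mean level per array (log2 units, centred on the mean of all arrays) of striated muscle and of squamous epithelium marker genes in the 10 groups; points are single arrays and bars are group means. The striated muscle level of the KO P5 hyperoxia lungs is 3.11 to 3.35 and their squamous level 2.07 to 2.62, 1 WT P5 air lung has 2.60 and 2.40, and 1 WT P5 hyperoxia lung has 2.19 and -0.46.

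The p53 and NRF2 targets also rose as sets in KO neonates by camera. Of the 23 lists that camera called for hyperoxia in KO, fry called 1. Eda2r rose by 2.53 (at least 1.82), the only one of 28 p53 targets called over all genes (6 adjusted over the list alone; mean 0.51, camera adjusted p = 1.56e-07; adjusted p = 0.124 with an estimated correlation). Of 29 NRF2 targets 11 were higher adjusted over the list alone (mean 0.56, and 0.86 without KO hyperoxia replicate 1; camera adjusted p = 2.43e-13; adjusted p = 0.102 with an estimated correlation). Ankrd37, a HIF target, was the only gene that fell, at -1.89. Without WT air replicate 3 and KO hyperoxia replicate 1, 92 genes were called and 37 of the 45 were among them; 8 of 28 p53 and 8 of 29 NRF2 targets then passed, which again follows in part from leaving out an array for its low levels of them, with Cdkn1a at 2.81, Gclc at 1.38 and Gpx2, an epithelial glutathione peroxidase, at 3.70. Pdgfra, the receptor of fibroblasts that make alveolar walls, was at -1.88 there.

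Limma called 45 genes in KO hyperoxia against air, 44 higher and 1 lower. Without KO hyperoxia replicates 1, 2 or 3 the counts were 73, 25 and 24, without KO air replicate 2 it was 23, with no offset 25, and a fit of the P5 groups alone called 0, with 781 genes at an unadjusted p under 0.05 in the fit of all arrays. Array weights gave 2680. The 18S control probe set differed between these groups too, at 229 to 1867 in air and 3542 to 15688 in hyperoxia.

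**Figure D4:**
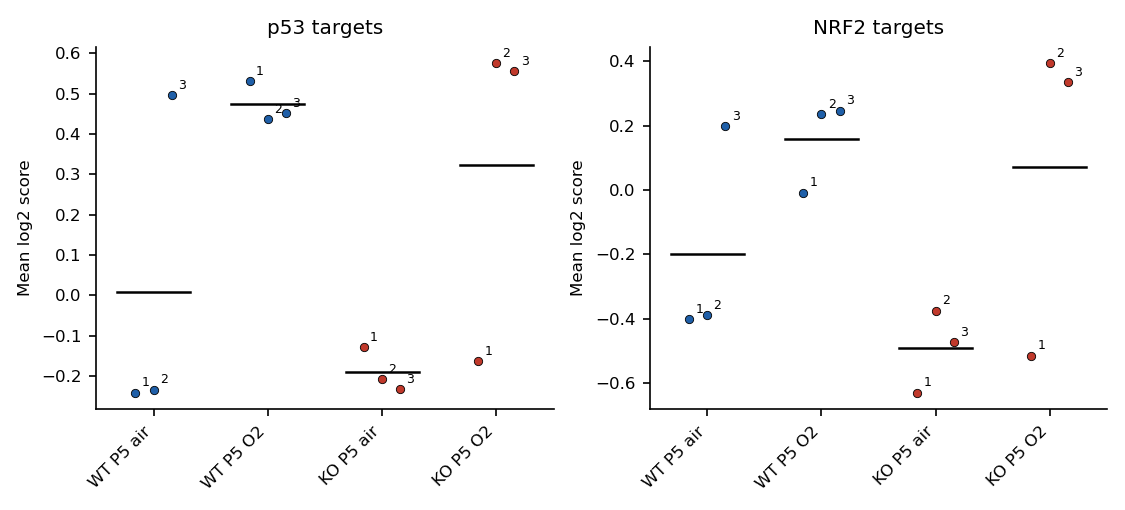
Mean level per array (log2 units, centred on the mean of all arrays) of the p53 and the NRF2 target lists in the 4 P5 groups (O2, hyperoxia); points are arrays with their replicate number and bars are group means. WT air replicate 3 has a p53 target level of 0.50 and KO hyperoxia replicate 1 of -0.16.

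The genotype-by-oxygen term asked whether the responses of KO and WT differ. The 18 genes called were all higher in the KO response, and 3 of them belong to the list of basal and keratinised epithelium and 3 to that of heart and skeletal muscle. Krt13 differed by 8.63 (SE 1.42; n = 3 in each of 4 groups), Krt4 by 7.86 and Krt5 by 3.86. The protease inhibitor Csta1 differed by 4.38, Crct1 by 3.58 and the desmosomal cadherin Dsc2 by 3.04. Myh8 differed by 6.002, Tnnt3 by 5.12, Actn3 by 3.57 and the calcium pump Atp2a1 by 3.44. Each of these genes lay under the median on every array of KO air, so the sizes depend on the offset: Krt13 differed by 6.415 to 10.85 and Myh8 by 5.01 to 6.71 with the other offsets. A high WT air lung adds to the differences: WT air replicate 1 read 2875 for Krt13, against 223 and 99.3 in replicates 2 and 3. For Myh8 it read 2293, against 181 and 46.5. The rise of Krt13 in KO alone was 5.52. Outside tissue as a source of the muscle and squamous genes stays open. By fry 0 lists were called for this term. Basal and keratinised genes differed as a set (3 of 16 over all genes, 7 adjusted over the list alone; camera adjusted p = 3.41e-17; adjusted p = 0.0463 with an estimated correlation). Mitotic and DNA replication genes differed by 0.55 and 0.57 on average, without a called member (camera adjusted p = 3.61e-16 and 2.11e-18; adjusted p = 0.192 and 0.122 with an estimated correlation). Without KO air replicate 1 these means were 0.31 and 0.28, and with array weights the mitotic response of KO itself went from 0.22 to -0.0610. The muscle list differed by 1.45 (3 of 26 over all genes, 9 adjusted over the list alone; camera adjusted p = 3.39e-10; adjusted p = 0.270 with an estimated correlation), and by 0.89 without WT hyperoxia replicate 1.

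Across 13345 genes, which are not independent replicates, the WT and KO responses at P5 correlated at r = 0.157 (Spearman 0.212). Without the 2 arrays named above r was 0.2505. The interaction count was 7 without WT air replicate 1, 33 without WT air replicate 3, 6 and 10 without WT hyperoxia replicates 1 and 2, 8 and 9 without KO air replicates 2 and 3, and 10 without KO hyperoxia replicate 1. It was 7 with no offset, 30 without both arrays named above, 0 in a fit of the P5 groups alone and 700 with array weights.

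Among exposed neonates limma called 25 genes between KO and WT, 23 higher in KO and 2 lower. Krt13 read 2327 ± 884 in KO and 25.8 ± 2.25 in WT (SD, n = 3 and 3), a change of 5.43 (at least 4.47, and not called with no offset), with Krt4 at 5.06 (at least 5.02), Myh8 at 4.08, Tnnt3 at 3.23 and the plakophilin Pkp1 at 2.97 (at least 1.19). Of 16 basal and keratinised epithelium genes 3 rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.26e-13; adjusted p = 0.0868 with an estimated correlation). Of 26 heart and skeletal muscle genes 3 rose (8 adjusted over the list alone; camera adjusted p = 8.41e-13; adjusted p = 0.205 with an estimated correlation), with a mean of 1.28, and of 0.72 without WT replicate 1. Outside tissue stays open as a source of the muscle and squamous genes here too. Gsr and Afp, the fetal plasma protein of liver, fell, Afp by 4.55 on the log2 scale. Neutrophil genes were lower as a set, with a mean of -0.89, and of -0.42 with the liver covariate (8 of 24 adjusted over the list alone, camera adjusted p = 6.88e-20, adjusted p = 0.0857 with an estimated correlation). The 18S control probe set separated these groups, at 17441 to 18961 in WT and 3542 to 15688 in KO, and the list changes were not adjusted for it. The count was 3 without WT replicate 1 or 2 and 6, 4 and 6 without KO replicates 1, 2 and 3; it was 7 with no offset, 3 with the liver covariate, 5 in a fit of the P5 groups alone, 43 in a fit of the 2 groups alone and 11 without the 2 arrays named above. The NRF2 target list, lower in KO by camera with a mean of -0.09 (adjusted p = 0.616 with an estimated correlation), moved with the arrays left out: its mean was 0.21 without KO replicate 1, -0.25 and -0.22 without KO replicates 2 and 3, -0.17 without WT replicate 1, and -0.05 and -0.04, not called, without WT replicates 2 and 3.

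In adults raised in air limma called 8 genes between KO and WT (n = 3 and 3). Gsr fell by 2.35, Papss2, which makes the sulphate donor of sulphation, by 1.16, the kinase Pomk by 0.91 and the exchange factor Cyth3 by 0.88 on the log2 scale. Actb rose by 0.90, Saraf by 0.82, the translation factor Eif4g2 by 0.69 (other probe sets -0.21, 0.26 and 0.38) and the ribosomal protein gene Rps3a1 by 0.54. Papss2 read 294 ± 48.1 in KO and 692 ± 156 in WT (SD), and Pomk 212 ± 9.54 and 422 ± 21.6. Oxidative phosphorylation genes were higher as a set by 0.31 (6 of 39 adjusted over the list alone; camera adjusted p = 1.43e-06; adjusted p = 0.855 with an estimated correlation), and club and secretory genes by 0.66 (3 of 18 adjusted over the list alone; camera adjusted p = 0.000154; adjusted p = 0.844 with an estimated correlation). Some markers of fat and heart moved in the same direction without being called by limma, Adipoq by 2.42 (adjusted p = 0.0985), the brown fat gene Ucp1 by 2.36 (0.298) and Myl7 by 1.19 (0.410). The heart level did not separate the groups, at 0.67 to 0.80 in KO and 0.86 in WT replicate 3. Whether other tissue adds to the list changes was not tested. The club mean was 0.19, not called, without WT replicate 2 and 1.17 without WT replicate 3. The actin 3'/5' ratio was 2.20 ± 0.212 in these KO lungs and 1.39 ± 0.126 in WT (SD). WT replicates 1 and 2 had low Xist, 506 and 387 units, with Y-linked Eif2s3y at 1548 and 1992. WT replicate 3 had 8524 and 130. Every KO array had high Xist, 5598 to 11567, and only KO replicate 1 also had high Eif2s3y, 1396. Genotype thus went largely with these levels, and sex is not among the labels. With the Y-linked level as a covariate the count was higher, as given below. With quantile normalization 2 genes were called; Rps3a1 was then at 0.02 and Actb at 0.34. In a fit of these 2 groups alone 1201 were called and in a fit of the P56 groups alone 1. The count was 1 without any of the WT replicates or KO replicate 1, 2 without KO replicate 2 and 5 without KO replicate 3; without the 2 arrays of highest 3'/5' ratio it was 502.

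The adult comparison of mice that had breathed oxygen as neonates with mice kept in air asked what remained of the exposure. Limma called 0 genes in WT, with 676 at an unadjusted p under 0.05, 0 in KO with 363, and 0 for the genotype-by-oxygen term with 330 (n = 3 per group). In WT, chemokine and acute inflammation genes were higher as a set by 0.54 (5 of 27 adjusted over the list alone; camera adjusted p = 2.71e-09; adjusted p = 0.144 with an estimated correlation), and endothelial genes lower with a mean of -0.38 (camera adjusted p = 4.98e-06; adjusted p = 0.661 with an estimated correlation). Both lists differed between the genotypes by camera, the chemokine list by -0.38 (camera adjusted p = 0.000116; adjusted p = 0.689 with an estimated correlation) and the endothelial list by 0.34 (0.00402; adjusted p = 0.855 with an estimated correlation). Adipoq was higher by 2.60 in exposed WT lungs (adjusted p = 0.473; at least 443 units against at most 434 in air), and Ucp1 read 2.19 to 1461 there. Without WT hyperoxia replicate 2, whose mean log2 3'/5' ratio was 2.84, the endothelial mean was -0.16 in WT and the difference 0.11, which was not called. In KO, T and NK lymphocyte genes were lower with a mean of -0.29 (camera adjusted p = 3.20e-06, adjusted p = 0.555 with an estimated correlation). The heart level of these KO lungs was lower too, at 0.67 to 0.80 in air and -0.89 to -0.41 in hyperoxia. The 18S control probe set read 2612 to 8395 in KO air and 342 to 636 in KO hyperoxia. The list change was adjusted for neither. The exposed groups held arrays with high Xist alone, 5960 to 12987 units in all 6, whereas 2 of 3 WT air arrays had Y-linked Eif2s3y above 1500. Sex is not among the labels, and the compared WT groups differ in these levels. Without WT air replicate 3 the WT count was 4 and without WT hyperoxia replicate 1 it was 3; a fit of the 2 KO groups alone called 44.

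Across genes the adult oxygen responses of WT and KO correlated at r = 0.267 (Spearman 0.186). Among exposed adults KO differed from WT in 4 genes (n = 3 and 3). Gsr was at -2.38, Saraf at 1.23, the predicted gene Gm5617 at 1.40, and Cyp26b1, an enzyme that breaks down retinoic acid, rose by 2.54 (SE 0.44; 928 ± 421 against 138 ± 71.6, SD). Gm5617 falls outside the rule by which genes were named and was chosen after its values were seen. The count was 2 without WT replicate 3 or KO replicate 3 and 8 without KO replicate 1. It was 349 with the 3'/5' ratio as a covariate.

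The wild-type air groups give the course of gene expression with age. From E19 to P5, lymphocyte, antigen-presenting and vascular genes rose. The T cell chemokine Ccl5 read 6.07 ± 1.97 at E19 (n = 4) and 359 ± 144 at P5 (SD, n = 3), a change of 3.51 (SE 0.38), or of at least 1.77, and Ms4a4b changed by 3.83 (at least 2.40). Of 24 T and NK genes 13 rose and 1 fell (13 and 1 adjusted over the list alone), and of 24 MHC class II and dendritic genes 8 rose (8 adjusted over the list alone), with the invariant chain Cd74 at 2.69 and H2-Aa at 2.38. Endothelial genes rose in 18 of 31 cases (21 higher and 1 lower adjusted over the list alone), with Hpgd, which breaks down prostaglandins, at 2.89. Alveolar macrophage genes rose in 11 of 25 cases and fell in 1 (14 and 4 adjusted over the list alone), with Itgax at 2.54 (at least 2.01). Type 1 genes rose in 10 of 24 cases and fell in 2 (11 and 3 adjusted over the list alone), led by Rtkn2 at 2.57 and Igfbp2 at 2.26. Camera adjusted p were 6.70e-07 for T and NK, 0.000373 for MHC class II, 9.07e-11 for endothelial, 3.00e-05 for macrophage and 0.00886 for type 1 genes; with an estimated correlation the adjusted p were 0.116, 0.180, 0.118, 0.180 and 0.489. The type 1 list lost its call without WT E19 replicate 4 (mean 0.35) and without WT P5 air replicate 3 (0.39).

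HIF and hypoxia genes fell after birth in 17 of 30 cases and rose in 1 (19 and 1 adjusted over the list alone), with Ndrg1 at -2.50, the glycolytic Aldoc at -2.05 and Bnip3 at -1.76, while Epas1, which encodes the endothelial HIF subunit, rose by 1.17 (camera adjusted p = 2.02e-10; adjusted p = 0.116 with an estimated correlation). Of 18 glucocorticoid response genes 8 fell and 2 rose (10 and 2 adjusted over the list alone), with Zbtb16 at -2.35 and Hif3a at -2.58 (camera adjusted p = 0.000373; adjusted p = 0.216 with an estimated correlation). The embryonic globin Hbb-y fell by 3.33 (at least 1.998) on the log2 scale, Dlk1, a gene of immature tissues, by 3.29 and the stress hormone gene Crh by 3.31 (at least 1.91). In all 1946 genes were called, 1113 higher and 833 lower. Without WT P5 air replicates 1 or 2 the count was 1249 and 1030, without the 2 arrays of highest 3'/5' ratio, neither of which is compared here, 3423, and in a fit of the E19 and P5 groups 1185.

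From P5 to P56, genes of dividing cells fell and immune and detoxification genes rose in WT air lungs. Of 35 mitotic genes 34 fell (35 adjusted over the list alone), with Cdk1 at -3.25 and Top2a at -3.00, and of 36 DNA replication genes 32 fell (33 adjusted over the list alone). Genes of matrix assembly fell too: 21 of 33 collagen and matrix genes fell and 1 rose (21 and 1 adjusted over the list alone), with Col1a1 at -2.57, and 16 of 28 elastic fibre and myofibroblast genes fell and 3 rose (20 and 3 adjusted over the list alone), with elastin Eln at -1.97, the fibrillin Fbn2 at -3.44 and Tnc at -3.46. Eln read 14015 ± 1440 at P5 and 3552 ± 349 at P56 (SD, n = 3 and 3). The antibody genes Igha and Jchain rose by 5.41 and 5.04 (Jchain by at least 4.59). Of 24 MHC class II and dendritic genes 20 rose and 1 fell (21 and 1 adjusted over the list alone), with H2-Eb1 at 3.22, and of 24 T and NK genes 20 rose (21 adjusted over the list alone). Interferon response genes rose in 25 of 36 cases (26 adjusted over the list alone, with 1 lower), with Ifit1 at 2.11. Cytochrome P450 and xenobiotic genes rose in 16 of 21 cases (17 adjusted over the list alone), with Cyp2b10 at 4.69, and ciliated cell genes in 18 of 27 (22 adjusted over the list alone). Sod3, the extracellular superoxide dismutase, rose by 3.68, and Gsr itself by 0.76 (SE 0.18).

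The calls of mitotic, DNA replication, MHC class II, T and NK, and P450 genes from P5 to P56 held with an estimated correlation, with adjusted p of 0.0145, 0.0318, 0.00466, 0.0173 and 0.0281. Those of the elastic fibre, collagen, interferon and ciliated lists had adjusted p of 0.0966, 0.168, 0.168 and 0.236 there, against camera adjusted p of 6.16e-08, 2.14e-08, 1.94e-10 and 3.77e-08. In all 3052 genes were called, 1610 higher and 1442 lower. The count was 1662 with the liver covariate and 5618 in a fit of the 2 groups alone.

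**Figure D5:**
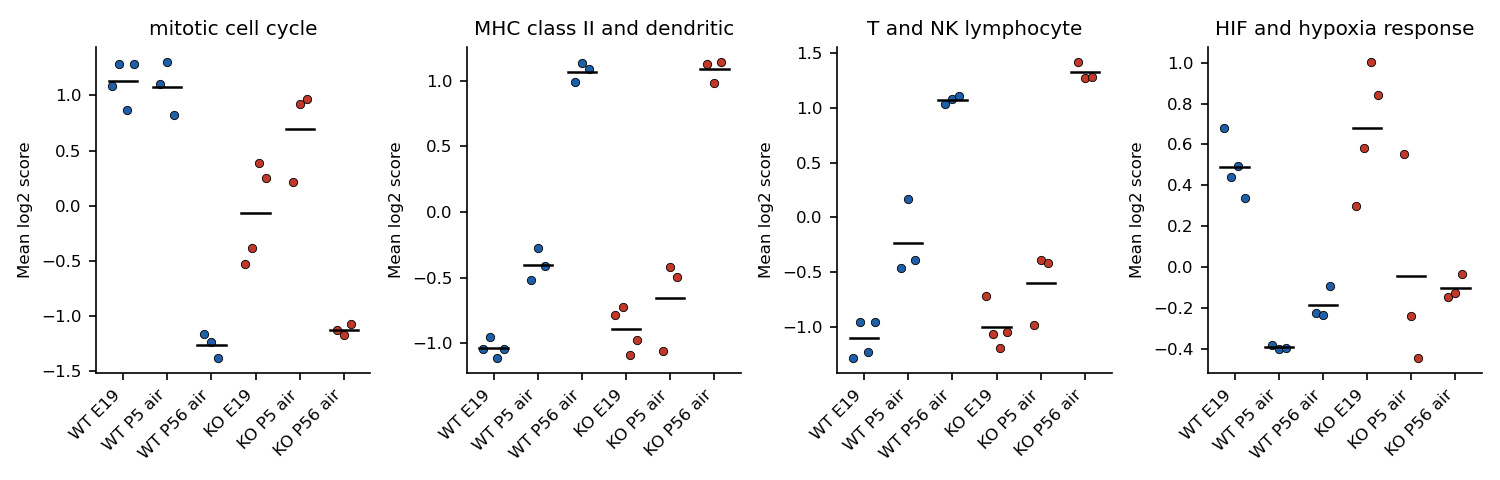
Mean level per array (log2 units, centred on the mean of all arrays) of gene lists at E19, P5 and P56 in air, WT and KO; points are single arrays and bars are group means. In WT the mitotic level lies between 0.83 and 1.31 at P5 and between -1.38 and -1.17 at P56, and the MHC class II level between -0.52 and -0.28 at P5 and between 0.99 and 1.13 at P56.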

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

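Chosen after the results were seen were the tests of other splits of the arrays, of an exchange of arrays, of the place of an array between groups, of poor RNA in KO E19 replicate 1 and of heart tissue; the tests of liver tissue, of shared WT arrays and of muscle with squamous epithelium were written before. Decision rules for the liver tests and for the muscle with squamous test were tightened after a first run, as said beside them.

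WT P5 air replicate 3 had p53 and NRF2 target levels of the hyperoxia lungs, and KO P5 hyperoxia replicate 1 those of the air lungs. An exchange of the WT array with a WT hyperoxia array has against it that 0 of those arrays had a p53 level as low as the other air lungs. That test takes every air lung to have a low p53 level. An exchange of the 2 arrays with each other is excluded by the Gsr signal of 890 in the WT array, above the KO maximum of 257. A wrong exposure label of either array stays open: over genes outside the p53, NRF2 and tissue lists the WT array lay at 0.76 of the way from air to hyperoxia (0.46 to 0.98 over the assignments of the other arrays) and the KO array at 0.30 (-0.21 to 0.66). Tissue levels went with the labels: the KO array had muscle and squamous levels of 3.35 and 2.26, against at most 0.22 and -0.13 in KO air, and the WT array had a liver level of 2.48, above the -0.07 to 1.46 of WT hyperoxia. Correlations over all tested genes went the other way. The WT array was closest to WT hyperoxia replicate 3 (r = 0.986, at most 0.981 with its own group). The KO array was closest to KO air replicate 3, by a small margin (r = 0.9819, at most 0.9815 with its own group). A mislabelled array and a difference between animals in the response to oxygen cannot be told apart, because each side holds 1 array, the assignments of the others move its place across the middle, and WT air replicate 1 carried muscle and squamous genes without oxygen, so the labels were kept.

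At E19, liver, erythroid and mitotic genes were lower and lung maturation genes higher in KO, and liver transcripts were high in 3 of 4 WT lungs, while WT replicate 1 (-0.22) lay within the KO range of -2.13 to 1.57. Poor RNA of KO replicate 1 as the whole source is excluded, as 1299 of the 2023 genes were called without it. The likeness to the change from E19 to P5 remained with the shared WT arrays divided (mean r 0.30, 0.12 to 0.46 over 6 divisions). The same arrays entering both comparisons were thus not its only source. Each division left a WT lung of high liver level in both comparisons, so a likeness apart from liver tissue was not shown. With the liver transcript level as a covariate the mean change was -1.07 for mitotic (95% interval -1.55 to -0.59, 89.2% left) and 0.28 for aerocyte genes (0.03 to 0.53, 55.1% left). Both lists were called, which argues against liver tissue as their whole source. For erythroid genes the mean was -0.58 (-1.12 to -0.05, 42.3% left), still called. Their level in WT replicate 1 lay below that of the other WT lungs, so liver tissue as their whole source stays open. The endothelial mean went from 0.28 (-0.06 to 0.63) to 0.0137 (-0.41 to 0.44) and the club mean from 0.73 (-0.02 to 1.47) to 0.12 (-0.79 to 1.04), and both calls ended as the means shrank. The rule written beforehand, more than 0.5 of the change left and the list called, was met by mitotic and maturation genes, but the intervals reach below 0.5 of the change (-0.60 for mitotic genes), so the rule was tightened and liver tissue stays open as a part of the source. How much of each change is liver tissue and how much a genotype effect cannot be told apart, because no KO lung carries the high liver level and the 1 WT lung without it, whose mitotic level was 1.08, is a single array.

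Striated muscle and squamous keratin genes, judged by 11 and 8 measured markers, were high in all 3 KO P5 hyperoxia lungs and in WT P5 air replicate 1 (2.60 and 2.40), and WT P5 hyperoxia replicate 3 had 2.19 and -0.46. Heart tissue as their source is excluded, since 4 heart genes changed by -1.29 (95% interval -2.96 to 0.39). Pieces of an outside tissue with muscle and squamous epithelium, a candidate source, were tested in the 20 E19 and P56 arrays, where the levels correlated within groups at r = 0.73 (permutation p = 0.0433). The rule written beforehand, r above 0.5 with p under 0.05, was met but then tightened because r was 0.22 without WT E19 replicates 1 and 2 and the Spearman correlation was 0.37 (p = 0.238). Both levels were also high in WT E19 replicate 1 (1.27 and 2.81). In that lung and in WT P5 air replicate 1 they were high without oxygen and without the knockout. For the KO hyperoxia lungs, outside tissue and a change of the lung itself cannot be told apart, since 2 arrays carry the test.

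Other splits of the same arrays were counted, the real split included. As many genes were called in 1 of 35 splits at E19 (2023, highest other 1271), in 1 of 35 from E19 to P5 in WT (1946, highest other 1414) and in 1 of 100 for the genotype-by-oxygen term at P5 (18, highest other 15). These shares are under 0.05 but are the lowest that 35 or 100 splits can give, and were not adjusted over the comparisons. The splits for the term exchanged KO and WT arrays within each exposure, which also breaks the genotype difference. High counts of other splits point to structure among the arrays, so chance is not excluded. For the term at P56 the real count was 0 (330 by limma at an unadjusted p under 0.05), so all 100 of 100 splits gave as many and the count says nothing of chance; another split gave 78, which points to structure of the samples. The other comparisons have 10 splits, too few for a share under 0.05. In these, 1 split gave as many for KO against WT in P5 air (2, highest other 0), P5 hyperoxia (25, highest other 0), P56 air (8, highest other 0) and P56 hyperoxia (4, highest other 1), for hyperoxia in KO at P5 (45, highest other 25) and from P5 to P56 in WT (3052, highest other 0). In WT at P5 it was 2 splits (1, highest other 10), and for hyperoxia at P56 10 in WT (0, highest other 9) and 10 in KO (0, highest other 0), where limma gave 676 and 363 genes at an unadjusted p under 0.05. The 1 other split of the WT arrays at P5 that called genes gave 10 against 1, which points to structure of the samples.

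An array far from the 3 others of its group was found in 19 of 246 sets of 4 values at E19, where chance gives about 1 in 20. In WT the log2 levels were 12.42 for Scd1, 7.01 for Sgpp2, 6.63 for Cyp1a1 and 12.27 for Epas1 in replicate 4, with list levels of -0.50 for type 2, -1.09 for aerocyte and -0.30 for lipofibroblast genes. They were 6.98 for Ifit3 and 10.94 for Inmt in replicate 3, 9.76 for Xaf1 and 5.735 for Itgax in replicate 2, and 7.34 for Apoa1 and 7.99 for Ttr in replicate 1. In KO they were 10.015 for Nusap1 in replicate 3, 6.495 for Ttr in replicate 2 and 10.85 for Vwf in replicate 4. The p53 list level was -0.45 in KO replicate 1, whose mean log2 3'/5' ratio was 4.37, and the lipofibroblast level was 0.0533 in KO replicate 3.

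The oxygen response at P5 differed between the genotypes, by test of the difference, in 18 genes. No call held in a fit of the P5 groups alone, and outside tissue as a source of the muscle and squamous genes stays open. They were Krt13 (8.63), Krt4 (7.86), Myh8 (6.002), Tnnt3 (5.12), Csta1 (4.38), 2300002M23Rik (3.89), Krt5 (3.86), Crct1 (3.58), Actn3 (3.57), Atp2a1 (3.44), Dsc2 (3.04), Cnfn (2.96), Krtdap (2.91), Ryr1 (2.82), Ifit1bl1 (2.79), Sypl2 (2.43), Cilp (2.34) and Asb5 (1.88). By camera the mean difference was positive for the lists of basal and keratinised epithelium (2.19), heart and skeletal muscle (1.45), DNA replication (0.57), mitosis (0.55), MHC class II (0.30), smooth muscle (0.30), platelets (0.28), T and NK cells (0.24) and B lymphocytes (0.23). It was negative for ciliated (-0.58), glucocorticoid (-0.49), immediate early (-0.38), neutrophil (-0.32), HIF (-0.30), type 2 (-0.30), circadian (-0.26), interferon (-0.24), lipofibroblast (-0.17), P450 (-0.17) and type 1 genes (-0.12). At P56 it was -0.65 for club, -0.38 for chemokine, -0.28 for chaperone and -0.19 for mitotic genes and 0.34 for endothelial genes. Of the list calls 11 of 20 at P5 and 2 of 5 at P56 held without any 1 of the arrays compared. With an estimated correlation the call of basal and keratinised epithelium held, at an adjusted p of 0.0463, and the others did not. By fry 0 lists were called for the term at P5, so that call did not hold there, and 0 at P56.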

How the results depend on the processing

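Chosen after the results were seen were the 3'/5' ratio and the liver level as covariates, the fit of the ages compared, the fits without the 2 P5 arrays, without the 2 arrays of high 3'/5' ratio or without all 4, and the lists with each array left out; the other alternatives were planned. Counts are genes called by limma, and where a count moved over 1.5-fold the cause was not tested. Fits of fewer groups take the spread from fewer arrays and from those groups alone, and their counts moved in either direction. The spread differed between groups: the lowest correlation of an array with its own group averaged 0.868 in KO E19 and 0.983 in KO P56 air. A spread shared by all groups therefore need not hold for each comparison. Dim probe sets carry no detection calls, so signal over background could not be separated on single arrays. With the stricter filter every count stayed within 1.5 times its value.

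Without a filter hyperoxia in WT at P5 gave 0, at P56 1, and in KO at P56 1. With no offset it gave 0 in WT and 25 in KO at P5, with 7 for the genotype-by-oxygen term and 7 for KO against WT in P5 hyperoxia. With an offset at the median of all values KO against WT in P5 air gave 4, and hyperoxia at P56 2 in WT and 3 in KO. Quantile normalization gave 0 for hyperoxia in WT at P5 and 2 for KO against WT in P56 air, as did centring on the medians (0 and 2), and no variance trend gave 2 for the latter. Testing every kept probe set gave 9 for P5 air, 0 for hyperoxia in WT at P5, 16 for P56 air, 2 for hyperoxia in KO at P56 and 9 for P56 hyperoxia, KO against WT. The replicate block gave 0 for hyperoxia in WT at P5 and 4 for P56 air. The Y-linked level as a covariate gave 4 for P5 air, 0 for hyperoxia in WT at P5, 10 for the term at P5 and 48 for P56 air.

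Array weights gave 1287 at E19; for KO against WT 1433 in P5 air, 1760 in P5 hyperoxia, 2691 in P56 air and 4717 in P56 hyperoxia; for hyperoxia 3223 in WT and 2680 in KO at P5, and 888 and 459 at P56. They gave 700 and 329 for the terms at P5 and P56, and 4743 and 7619 for the steps of age. List means that changed sign with array weights, none of them called then, were for hyperoxia in KO at P5 mitotic (-0.0610), type 2 (0.0364), ciliated (0.1605), B lymphocyte (-0.0162), platelet (-0.0124) and glucocorticoid genes (0.0763), for the term at P5 B lymphocyte genes (-0.0314), and in P5 hyperoxia NRF2 (0.0682) and p53 targets (0.0583). The groups compared alone gave 40 at E19, 0 for P5 air, 0 for hyperoxia in WT at P5, 0 for the term at P5, 43 for P5 hyperoxia, 1201 for P56 air, 44 for hyperoxia in KO at P56, 1 for P56 hyperoxia and 5618 from P5 to P56. The groups of the ages compared gave 40 at E19, 64 for P5 air, 0 for hyperoxia in WT and 0 in KO at P5, 0 for the term, 5 for P5 hyperoxia, 1 for P56 air, 4 for hyperoxia in KO at P56, 8 for P56 hyperoxia and 1185 from E19 to P5.

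The liver level as a covariate gave 248 at E19, 1 for P5 air, 0 for hyperoxia in WT at P5, 3 for P5 hyperoxia, 13 for P56 air and 1662 from P5 to P56. It reversed Ttr at E19 (0.44), Apoa1 (0.16) and Serpina1b (0.53) from P5 to P56, and the erythroid list in P5 air (0.46). Means of lists that lost their call changed sign too: ciliated (-0.0690) and collagen genes (-0.152) at E19; ciliated (-0.0332), neutrophil (0.161) and interferon genes (-0.0536) in P5 air; club (-0.265) and cholesterol genes (0.0357) for hyperoxia in WT at P5; and the list of brown fat, thymus, liver and pancreas in P5 hyperoxia (0.119). The 3'/5' ratio as a covariate gave 4 for P5 air, 477 for P56 air, 1 for hyperoxia in KO at P56, 349 for P56 hyperoxia, 3408 from E19 to P5 and 4633 from P5 to P56. Without the 2 arrays of high 3'/5' ratio (KO E19 replicate 1 and WT P56 hyperoxia replicate 2) the counts were 5 for P5 air, 502 for P56 air, 2 for hyperoxia in KO at P56, 8 for P56 hyperoxia, 3423 from E19 to P5 and 4603 from P5 to P56. Without the 2 P5 arrays they were 17 for hyperoxia in WT and 92 in KO at P5, 30 for the term, 11 for P5 hyperoxia, 1 for P56 air and 2 for hyperoxia in KO at P56. Without all 4 they were 54 and 196 for hyperoxia in WT and KO at P5, 8 for P5 hyperoxia, 433 for P56 air, 1 and 4 for hyperoxia in WT and KO at P56 and 7 for P56 hyperoxia. In P5 hyperoxia the NRF2 list reversed without the 2 P5 arrays (0.21), with or without the other 2, and so did, without a call, the means of the p53 (0.0915), glutathione (0.0158), type 1 (0.0210), club (0.0343) and P450 lists (0.0605).

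Leaving out each array in turn gave 1140 to 2768 genes at E19, 2 to 5 for P5 air, 0 to 7 and 23 to 73 for hyperoxia in WT and KO at P5, 6 to 33 for the term at P5, 3 to 24 for P5 hyperoxia, 1 to 5 for P56 air, 0 to 4 and 0 to 0 for hyperoxia in WT and KO at P56, 0 to 0 for the term at P56, 2 to 8 for P56 hyperoxia, 1030 to 2200 from E19 to P5 and 2117 to 2764 from P5 to P56. Camera called 206 lists in all, against 11 with an estimated correlation, 56 with fry and 194 to 220 with an array left out. Of the lists called, those called without any 1 of the arrays compared were 14 of 25 at E19, 8 of 20 in P5 air, 15 of 22 and 9 of 23 for hyperoxia in WT and KO at P5, 11 of 20 for the term at P5, 9 of 22 in P5 hyperoxia, 5 of 10 in P56 air, 3 of 6 and 2 of 6 for hyperoxia in WT and KO at P56, 2 of 5 for the term at P56, 1 of 2 in P56 hyperoxia, 13 of 22 from E19 to P5 and 23 of 23 from P5 to P56. The mean changed sign without 1 array for 2 lists at E19, 1 in P5 air, 3 and 6 for hyperoxia in WT and KO at P5, 2 for the term at P5 and 6 in P5 hyperoxia, and for 0 in the others. Within 5 Mb of Gsr the share called in P5 hyperoxia had Fisher's exact p = 0.0442. Named genes kept direction and call in 2962 cases and lost the call in 520 when an array was left out. They kept both in 472 cases and lost the call in 25 with quantile normalization, in 315 and 182 with the groups compared alone, and in 324 and 170 with the liver covariate.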

Other observations

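The comparison of the E19 genotype difference with the first days of life in WT was made after the result was seen, apart from the test with divided WT arrays.

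Rtkn2 changed by 2.60 with genotype at E19 and by 2.57 from E19 to P5 in WT, and Car4 by 1.601 and 2.27. The comparisons share the WT E19 arrays, which alone gave r = 0.463 in simulated data against 0.480 in the real data. In simulated noise of equal spread this r follows from the numbers of arrays, so it does not measure their part in the real r. The covariance was 0.158 in the real data and 0.0346 on average in the simulated data. With the arrays divided the mean r was 0.302, 54.5% to 59.9% of genes had the same sign in both comparisons, and so had 14 to 16 of the 22 lists called from E19 to P5. Each division left a WT lung of high liver level in both comparisons, so these values do not show a likeness apart from liver tissue. The hypothesis that KO lungs were ahead in development at E19 could hold for alveolar type 1 and aerocyte genes, of whose changes 54.1% and 55.1% were left with the liver covariate. For the endothelial list 4.85% was left. That does not decide, as the interval with the covariate, -0.41 to 0.44, holds the whole uncorrected mean of 0.28. HIF targets, which fell after birth, were higher in KO at E19 (0.19, adjusted p = 0.542 with an estimated correlation), which goes against the hypothesis. The HIF list was not called without KO replicate 3 or 4. The mean change of the mitotic list was -1.197 in KO at E19. That list was not among those called from E19 to P5 in WT, but its mean change from P5 to P56 was -2.34. The lower mitotic level in KO therefore does not decide for or against the hypothesis.

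Lists of the NADPH-producing enzymes and of thioredoxin, peroxiredoxin and superoxide enzymes were not called by camera in any of the 13 comparisons. Across 13345 genes the genotype difference at E19 correlated with that in P5 air at r = 0.523 (Spearman 0.303) and with that in P56 air at r = 0.0162 (Spearman -0.0433). Liver transcripts, higher on average in WT in E19 and in P5 air lungs, are among the genes of the former.

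WT P5 hyperoxia replicate 3 read 5229 for Xist and 1873 for Y-linked Eif2s3y, and KO P56 air replicate 1 read 5598 and 1396. The control probe set for the 5' part of 18S ribosomal RNA had mean signals of 17382 and 5614 in WT and KO at E19 and of 18060 and 869 in P5 air. In KO it also differed with oxygen, without overlap, from 869 in air to 8370 in hyperoxia at P5 and from 5978 to 462 at P56. Of 32 arrays 10 correlated most closely with an array of another group.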
